A study of Mus musculus with 8 samples.

How the data were processed

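Polyadenylated RNA was measured in 8 mixed co-cultures of mouse splenocytes and sorted colon cancer cells, 4 with trogocytic and 4 with non-trogocytic cancer cells. Per the labels' protocols, libraries were made with a low-input kit and sequenced as paired-end reads of 100 bp. The submitters' processing notes name HISAT2, StringTie 1.3.3, DESeq version 2 and the mouse builds GRCm38 and mm10. The annotation release and the strand setting of the counting are not given in the sources used here, and counts of reads were not analysed here.

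Each deposited file is a gene abundance table of 1 library. Per the file headers it holds a coverage, an FPKM and a TPM for each gene. The deposited coverage is the mean read depth over the gene model, with no scaling. The deposited FPKM is that coverage per Gb of aligned bases, and the deposited TPM is scaled by the authors to the same sum in every library. For genes with 1 annotated transcript, coverage divided by FPKM was constant within a library, which gives 1.39 to 1.84 Gb of aligned bases per library, or 6.93 M to 9.21 M read pairs if every pair aligned over its full 200 bases. At that depth, 5.83 to 8.45 read pairs lie behind 1 TPM of a transcript of 2 kb, so levels of a few TPM rest on few reads. In the group of tested genes with a mean of 2 to 5 TPM, 29.5% had at least 1 library listed at 0. The share was 13.1% at 5 to 20 TPM and 0.9% at 20 to 100 TPM. Whether depth alone gave these zeros was not tested.

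The files held 52636 gene IDs, of which 49121 had the same version in the GENCODE M21 annotation of GRCm38, all of these with the same start and end. Symbols and coordinates are those of the files. TPM was summed over rows for the 10 IDs on more than 1 row. Genes with a TPM of at least 1 in 4 or more libraries were tested, which left 11433. The test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(TPM + 1), two-sided, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. Every fold change is trogocytic against non-trogocytic on the log2(TPM + 1) scale, which understates the change of low genes. No count model fits such values, so none was used here.

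Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 3 tested members, then with an estimated correlation and with fry. List means per library were compared with an exact permutation test over all splits of the 8 libraries into 4 and 4, two-sided, whose smallest p is 0.0286. The 47 lists cover cell types that a co-culture of spleen and tumour cells could hold, immune and tumour cell processes, signs of RNA quality and sex-linked genes. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

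Genes were named by a fixed rule with 3 parts. The first part takes up to 12 called genes per direction with a mean of at least 2 TPM in the higher group, no overlap between the groups and no clone-type symbol, or, where fewer than 5 qualify, the 5 with the smallest p in that direction, given as not passing. The second part takes, of each list, the 2 tested members with the smallest p and the 2 with the highest mean TPM. The third part is a panel of cell markers and immune regulatory molecules. The rule names 174 genes, of which a part is printed.

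On simulated log2 values for the 11433 genes with the real means and spreads and 200 changed genes, the test recovered 7.1% of genes changed by 1 on the log2 scale, 41.3% of those changed by 2 and 68.2% of those changed by 3, and 4.7% of its calls were false. Small changes of single genes were therefore mostly out of reach. The simulated noise was independent between genes and had no floor at 0, unlike the real values. With no change, the simulations called 0.1 genes and 0.1 lists on average. Other splits of the real libraries called up to 5 genes and a median of 5 lists. The 4.7% of false calls thus need not hold for the real libraries. Alternatives covered the unit, pseudocount, filter, scaling, variance model, gene identity, replicate block and each library left out in turn. Leaving out the first replicates of both groups, Ptprc as a covariate and the alternatives for list means were added after the data had been seen.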

Results

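RNA was sequenced from mixed co-cultures of mouse spleen cells (splenocytes) and colon cancer cells. The cancer cells came from organoids with a red fluorescent tdTomato reporter that had been injected into the spleen and had spread to the liver. They were sorted on tdTomato and on CD4, a surface protein of helper T cells, into trogocytic and non-trogocytic cells. Trogocytosis is the transfer of pieces of membrane and their proteins from one cell to another. Each sorted population was kept for 5 days with C57BL/6 splenocytes at 1 cancer cell to 50 splenocytes. There were 4 libraries per group, and the co-cultures with non-trogocytic cells were the control. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The libraries held 1.39 to 1.84 Gb of aligned bases, and 10867 to 12362 genes had at least 1 TPM. RNA came from the whole mixture, so each value sums over all cell types present.

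Transcripts of the cancer cells and of leukocytes were both present in every library, at levels that differed more between libraries than between groups. Krt18, a keratin of simple epithelia, stood at 3088 ± 1243 TPM (SD, n = 4) in non-trogocytic and 3358 ± 390 TPM (SD, n = 4) in trogocytic co-cultures. Epcam, an epithelial adhesion molecule, stood at 370.3 ± 101 and 347.5 ± 31.8 TPM. Ptprc, which encodes the leukocyte antigen CD45, stood at 152 ± 135 and 164 ± 64.8 TPM and ranged from 55.8 to 345 TPM over the libraries. None of these passed limma's test (adjusted p = 0.9998 for each). The mean of 15 colon epithelium and carcinoma genes differed by −0.10 ± 0.34 (SE) on the log2 scale, with an exact permutation p of 0.8286. The groups did not stand apart as a whole. The mean distance between libraries of different groups was 126.51 and that within groups 126.66 (exact permutation p = 0.4571, one-sided). Correlations of log2 values between 2 libraries ran from 0.853 to 0.912. The first principal component held 23.3% of the variance, and replicate 1 of each group had the highest scores on it, 0.572 and 0.5.

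The first comparison asked which genes differed between mixed co-cultures with trogocytic and with non-trogocytic cancer cells. Of 11433 genes, 6 were called, 2 higher and 4 lower in trogocytic co-cultures. The higher ones were Gsta1 and Gm3776, neighbouring genes on chromosome 9, of which Gsta1 encodes a glutathione transferase that detoxifies electrophiles. Among the lower ones were the chemokine gene Ccl6, Spp1, which encodes the secreted protein osteopontin, and Oit1. Gm3776, which has a clone-type symbol, was chosen after its values were seen. The number of genes with an unadjusted p below 0.05 was 525, against 571.6 expected by chance. In 306 tested genes, or 2.68%, the groups did not overlap, against 2.86% by chance.

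Ccl6 (ENSMUSG00000018927.3, chromosome 11, 83587882 to 83593087) fell from 2000 ± 657 to 276.8 ± 104 TPM (SD, n = 4 each), a log2 fold change of −2.87 ± 0.31 (SE, limma adjusted p = 0.014). Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050) fell from 2240 ± 464 to 784 ± 202 TPM, with a log2 fold change of −1.52 ± 0.21 (limma adjusted p = 0.0483). Oit1 (ENSMUSG00000021749.6, chromosome 14, 8348937 to 8378754) stood between 6.74 and 13.7 TPM in the non-trogocytic libraries. In the trogocytic group, it was listed at 0 in 3 libraries and at 0.869 TPM in replicate 4 (limma adjusted p = 0.0483). Gsta1 (ENSMUSG00000074183.3, chromosome 9, 78230656 to 78242684) rose from 99.9 ± 21.5 to 287 ± 20.96 TPM, a log2 fold change of 1.54 ± 0.20 (limma adjusted p = 0.0375). Gm3776 (ENSMUSG00000111709.1, chromosome 9, 78257129 to 78269166) rose from 68.8 ± 9.35 to 229.5 ± 12.1 TPM, a log2 fold change of 1.73 ± 0.18 (limma adjusted p = 0.014). These genes and Gsta2 are near-identical copies, so the division of reads among them is uncertain. The antisense genes that overlap Ccl6 and Oit1 stood at 0.019 and 0 TPM.

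**Figure D1:**
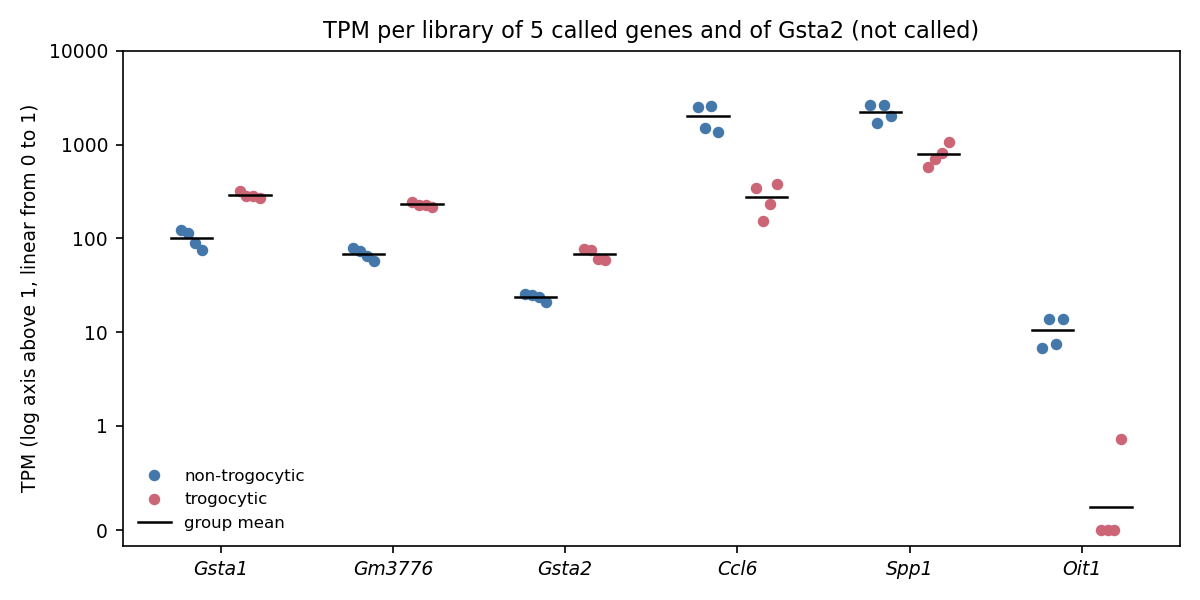
TPM per library (y axis, logarithmic above 1 and linear from 0 to 1) of 5 called genes and of Gsta2, which was not called. Each point is 1 library, blue for non-trogocytic and red for trogocytic co-cultures, and bars are group means. Ccl6 lies at 2000 TPM on average in the non-trogocytic and 276.8 TPM in the trogocytic libraries, and for each of these genes the groups do not overlap.

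Of genes next in rank that did not pass, Gsta2 stood at 23.8 ± 2.01 and 67.9 ± 9.52 TPM (limma adjusted p = 0.1068) and Dynap at 31.6 ± 6.63 and 74.1 ± 8.71 TPM (0.2916). Ddc, which encodes an enzyme of dopamine and serotonin synthesis, was listed at 0 in all 4 non-trogocytic libraries and at 2.86 to 16.2 TPM in the trogocytic ones (0.1691). The T cell receptor segment Trbj2-6 was likewise listed at 0 in the non-trogocytic libraries and at 1.54 to 5.77 TPM in the trogocytic ones (0.2542). It is annotated as a pseudogene from 41543598 to 41543645 on chromosome 6, shorter than 1 read of 100 bp. Its levels therefore rest on few reads. Ighg3, an antibody heavy chain gene, had the reverse pattern, with 6.09 to 39.5 TPM against 0 in each trogocytic library (0.0877). The number of calls fell whichever library was left out, where fewer samples are fitted. It was 0 without non-trogocytic replicate 3 or without trogocytic replicate 1, 2 or 3, 1 without trogocytic replicate 4, 2 without non-trogocytic replicate 2, and 3 without non-trogocytic replicate 1 or 4. It was also 2 with a pseudocount of 0.01, 1 with no filter, 1 without the mean-variance trend and 0 without the first replicates of both groups. A block for the replicate number left 0 calls, with and without median-of-ratios scaling.

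The second comparison asked which cell types and processes differed, over 41 fixed lists. With the preset correlation, camera called 11, 6 lower and 5 higher in trogocytic co-cultures. With an estimated correlation it called 0, with a smallest adjusted p of 0.2896 and 4 lists at an unadjusted p below 0.05. Fry called 0 for a shift in one direction, with 4 at an unadjusted p below 0.05, and 4 for changes in either direction, while the exact permutation test of list means called 0, with 3 at the smallest p it allows, 0.0286 (adjusted 0.3909), a floor that leaves it hardly able to call any of 41 lists. The directed calls thus hold only with the preset correlation. With it, the count was 6 without non-trogocytic replicate 2 and 7 without non-trogocytic replicate 4.

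Lists of macrophage genes were called lower in trogocytic co-cultures by camera with the preset correlation, while the exact test of the list mean reached its smallest p only for alternative activation. Of 8 tested genes of alternative macrophage activation, all 8 had a fold change below 0, and the list mean differed by −1.50 ± 0.40 (SE, n = 4 per group; exact permutation p = 0.0286). Camera's adjusted p was 9.06e-07, and the adjusted p was 0.2896 with an estimated correlation. Of its members, 1 fell over all genes tested, Spp1, and 4 fell when adjusted over the list alone. The others were Mmp12, Arg1 and Gpnmb. Mmp12, a macrophage elastase, went from 157 ± 76.2 to 17.9 ± 19.6 TPM. Gpnmb, a glycoprotein of lysosome-rich macrophages, went from 245 ± 134 to 83.6 ± 53.4 TPM. Arg1, which encodes arginase 1 and was chosen after its values were seen, stood at 52.3 ± 23.6 and 7.41 ± 10.2 TPM. The macrophage and monocyte list had 20 tested members, 16 with a fold change below 0, and 1 that fell when adjusted over the list alone, the antibody receptor gene Fcgr1 (7.39 ± 5.21 and 0.681 ± 0.936 TPM). Its camera adjusted p was 0.000335, with an adjusted p of 0.8104 with an estimated correlation. Its mean differed by −0.63 ± 0.49 (exact permutation p = 0.2857). Lyz2, the lysozyme of myeloid cells, stood at 6418 ± 4020 and 2334 ± 1305 TPM, and Apoe, an apolipoprotein, at 1468 ± 768 and 1022 ± 656 TPM. All 13 tested lysosome genes had a fold change below 0, among them the proteases Ctsl (168 ± 26.4 and 123 ± 22.4 TPM) and Ctsb (785 ± 366 and 416 ± 254.5 TPM) and the membrane protein Cd63 (1360 ± 475 and 935.5 ± 244 TPM). None of them passed alone, over all genes or adjusted over the list alone, and Ctsb overlaps Fdft1 on the other strand. The list's camera adjusted p was 3.4e-05, and the adjusted p was 0.8104 with an estimated correlation. The lysosome mean differed by −0.63 ± 0.43 (exact permutation p = 0.2). Among 11 chemokine genes, 8 had a fold change below 0, and when adjusted over the list alone Ccl6 and Ccl9 fell, the latter from 14.6 ± 5.49 to 3.30 ± 3.95 TPM. Ccl5, a chemokine of T cells, stood higher, at 180 ± 181 and 288 ± 156 TPM. The list's camera adjusted p was 0.00303, with an adjusted p of 0.5461 with an estimated correlation, and its mean differed by −0.85 ± 0.40 (exact permutation p = 0.1143). The camera value was 0.1275 without non-trogocytic replicate 1, 0.0562 without non-trogocytic replicate 3 and 0.1284 without the first replicates of both groups.

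Of the T cell lists, 3 were called higher in trogocytic co-cultures by camera with the preset correlation alone, and none of their members passed. The helper and CD8 lineage and regulatory T cell lists were not called (camera adjusted p = 0.1678 and 0.8437). Of 18 pan T cell genes, 16 had a fold change above 0, with a list difference of 0.68 ± 0.61 (SE; exact permutation p = 0.3429). Camera's adjusted p was 0.000315, and the adjusted p was 0.8104 with an estimated correlation. Trbc1 and Trbc2, constant segments of the T cell receptor beta chain, stood at 184 ± 33.7 and 257.5 ± 31.9 TPM and at 82.2 ± 66.3 and 148 ± 69.98 TPM. Trbc1 was little related to 16 other T cell markers over the 8 libraries (Pearson's r = 0.15, exact permutation p = 0.7188). Cd3g, of the receptor's signalling complex, stood at 57.8 ± 37.3 and 134 ± 96.4 TPM. All 10 naive and memory T cell genes had a fold change above 0 (camera adjusted p = 0.00278, and adjusted p = 0.8104 with an estimated correlation), with an exact permutation p of 0.2571 for the list mean, among them the lymph node homing receptor Ccr7 (8.04 ± 8.96 and 23.1 ± 13.1 TPM), Dapl1 (17.2 ± 10.7 and 47.1 ± 34.0 TPM), the interleukin 7 receptor Il7r (109 ± 97.4 and 142 ± 93.8 TPM) and Lef1 (38.7 ± 26.7 and 59.4 ± 39.3 TPM). Of 15 cytotoxic effector genes only 5 were tested, and these 5 also had a fold change above 0. Camera's adjusted p was 0.021, and 0.5461 with an estimated correlation, with an exact permutation p of 0.1429 for the list mean. Gzmb, which encodes granzyme B, was listed at 0 in all 8 libraries. Among the tested genes, Nkg7 stood at 41.4 ± 47.2 and 60.9 ± 31.9 TPM, Eomes at 1.29 ± 0.514 and 4.13 ± 3.74 TPM and Cst7 at 1.71 ± 2.34 and 6.65 ± 4.76 TPM. Eomes overlaps Gm33460 on the other strand, which stood at a mean of 8.113 TPM, so its reads are uncertain. The pan T cell list's adjusted p was 0.1348 without non-trogocytic replicate 4 and 0.0551 without trogocytic replicate 1. The naive and memory list's was 0.0752, 0.3015 and 0.1665 without non-trogocytic replicate 2, non-trogocytic replicate 4 and trogocytic replicate 1, and the cytotoxic list's was 0.228 and 0.164 without non-trogocytic replicate 2 and 4 and 0.0844, 0.0619 and 0.0611 without trogocytic replicate 1, 2 and 4. With Ptprc as a covariate, the naive and memory and the cytotoxic lists each had an adjusted p of 0.1223.

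**Figure D2:**
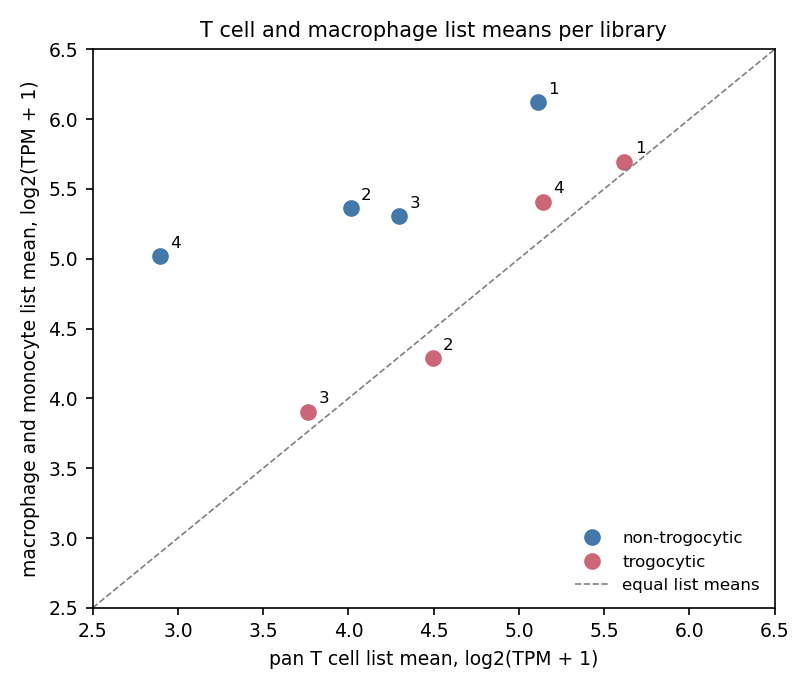
Mean log2(TPM + 1) of the pan T cell list (x axis) against that of the macrophage and monocyte list (y axis), 1 point per library with its replicate number, blue for non-trogocytic and red for trogocytic co-cultures. The dashed line marks equal means. The macrophage mean exceeds the T cell mean by 1.01 to 2.13 in the non-trogocytic libraries and lies between 0.208 below and 0.268 above it in the trogocytic ones.

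The plasma cell and type I interferon lists were also called lower in trogocytic co-cultures by camera with the preset correlation. Of 10 plasma cell genes, 9 had a fold change below 0, and Ighg3 alone passed when adjusted over the list alone. The antibody genes Igha and Jchain stood at 69.2 ± 56.9 and 24.07 ± 20.99 TPM and at 113 ± 75.9 and 64.8 ± 39.6 TPM, and Fkbp11 at 65.8 ± 27.1 and 40.0 ± 27.1 TPM. The list mean differed by −1.0014 ± 0.46 (SE; exact permutation p = 0.1143). The list's camera adjusted p was 0.000653, and the adjusted p was 0.2896 with an estimated correlation. The camera value was 0.0946 and 0.1048 without non-trogocytic replicate 1 and 2, and 0.1265 without the first replicates of both groups. Of 13 type I interferon response genes, 11 had a fold change below 0 and none passed alone, over all genes or adjusted over the list alone. Examples are Xaf1 (8.96 ± 3.78 and 2.11 ± 1.64 TPM), Rtp4 (28.0 ± 9.82 and 9.55 ± 7.75 TPM) and Bst2, which tethers budding viruses (66.0 ± 23.7 and 30.6 ± 19.5 TPM). Ddx58, the sensor of viral RNA known as RIG-I, stood higher without passing, at 8.75 ± 4.13 and 22.7 ± 5.33 TPM. The interferon list mean differed by −0.86 ± 0.20 (SE; exact permutation p = 0.0286), with a camera adjusted p of 0.00147 and an adjusted p of 0.2896 with an estimated correlation.

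Lists of sample makeup and RNA quality were called higher by camera with the preset correlation as well. All 4 tested sex-linked genes, which lie on the Y chromosome, had a fold change above 0, with a list difference of 0.50 ± 0.12 (SE; exact permutation p = 0.0286). Ddx3y stood at 61.1 ± 10.96 and 94.9 ± 21.01 TPM, Kdm5d at 2.96 ± 0.959 and 6.79 ± 3.47 TPM and Eif2s3y at 239 ± 40.6 and 273 ± 65.0 TPM. Xist, transcribed from the inactive X chromosome and in the same list, did not reach the filter and stood at 0.480 ± 0.345 and 0.0162 ± 0.0155 TPM. It stood at 0.516 to 0.849 TPM in non-trogocytic replicates 1 to 3. In non-trogocytic replicate 4 it stood at 0.016 TPM, within the trogocytic range of 0 to 0.036 TPM. A different share of male and female cells in the groups was not tested, and these libraries could not separate it from the grouping. The list's camera adjusted p was 0.0166, and the adjusted p was 0.2896 with an estimated correlation. The camera value was 0.0821 and 0.1143 without non-trogocytic replicate 2 and 4, 0.066 with the higher TPM filter and 0.0936 with Ptprc as a covariate. Of 12 mitochondrially encoded genes, 10 had a fold change above 0, among them mt-Cytb (2403 ± 1115 and 3515 ± 1006 TPM), mt-Nd2 (341 ± 169 and 467 ± 119.5 TPM) and mt-Co1 (955 ± 769 and 1277 ± 581 TPM). The camera adjusted p was 0.0433, and the adjusted p was 0.8205 with an estimated correlation, with an exact permutation p of 0.4571 for the list mean. This call was lost without non-trogocytic replicate 2 or 4 (0.5065 and 0.7887) or trogocytic replicate 1, 2 or 4 (0.2918, 0.0739 and 0.1705). It was also lost with the higher TPM filter, both rescalings and Ptprc as a covariate (0.05005 to 0.1032).

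**Figure D3:**
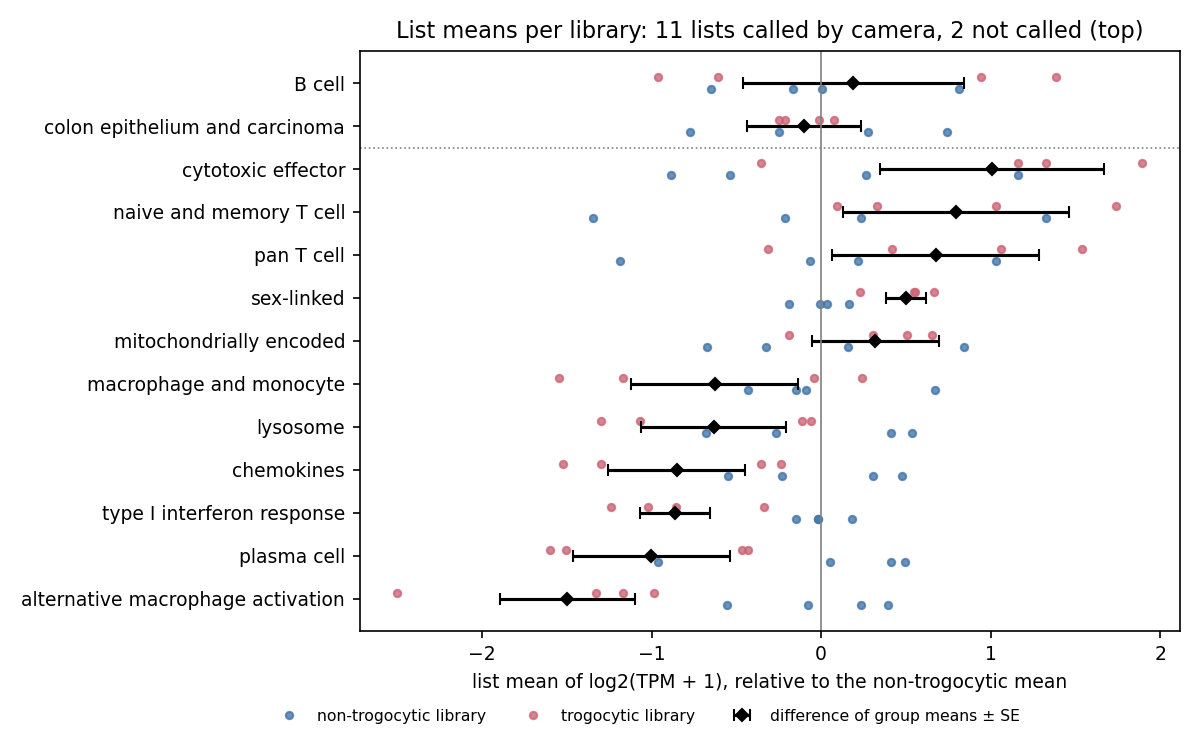
Mean log2(TPM + 1) of each list per library, relative to the non-trogocytic mean (x axis), for the 11 lists called by camera with the preset correlation and, above the dotted line, 2 lists that were not called. Small points are libraries, blue for non-trogocytic and red for trogocytic, and diamonds with bars are the difference of the group means ± SE. The alternative macrophage activation list differs by −1.50 and the colon epithelium list by −0.10.

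Genes of immune regulation were of interest because the cells were sorted on a protein acquired from T cells. None of the tested members of the panel passed limma's test. Tigit, an inhibitory receptor of T and natural killer cells, stood at 66.7 ± 19.2 and 83.6 ± 16.8 TPM, Havcr2 at 3.97 ± 2.87 and 7.31 ± 8.47 TPM and Vsir at 2.66 ± 2.27 and 2.80 ± 2.65 TPM. The ligand genes Cd274 and Cd86 stood at 5.60 ± 4.37 and 3.60 ± 3.89 TPM and at 19.8 ± 13.4 and 31.1 ± 19.0 TPM, and Cd8a at 2.59 ± 3.62 and 3.87 ± 2.99 TPM. Cd4, Ctla4, Pdcd1, Lag3 and Cd80 did not reach the filter. Lag3 was listed at 0 in all 8 libraries, and Ctla4 was listed at 0 in the 4 non-trogocytic libraries and at 0.255 to 7.30 TPM in the trogocytic ones. Ctla4 overlaps Rpl18-ps1 on the same strand, which stood at a mean of 2.397 TPM, so its reads are uncertain. Cd4 reached at most 1.46 TPM. Among 7 inhibitory receptors and checkpoint genes, 1 fell when adjusted over the list alone, Lgals9, which encodes galectin 9 (28.8 ± 10.7 and 6.70 ± 5.82 TPM), and Tox, a transcription factor of exhausted T cells, stood at 3.66 ± 2.46 and 8.67 ± 6.09 TPM. Of 10 costimulatory and checkpoint ligands none passed, over all genes or adjusted over the list alone. There, Pvr stood at 9.57 ± 6.02 and 16.5 ± 1.66 TPM and Tnfsf9 at 83.2 ± 36.0 and 57.8 ± 12.9 TPM. Neither list was called (camera adjusted p = 0.8962 and 0.9171).

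The remaining lists gave no call, with camera adjusted p-values from 0.1678 to 0.9864 over 30 lists. The colon epithelium and carcinoma list (0.889) included Elf3 at 10.01 ± 5.71 and 3.91 ± 2.78 TPM and Vil1 at 5.82 ± 2.21 and 2.96 ± 0.787 TPM. Vil1 overlaps Usp37 on the other strand, and the strand setting of the counting is not known. B cell genes (0.5955) included Cd72 at 20.8 ± 14.6 and 38.0 ± 14.6 TPM, Ebf1 at 5.20 ± 1.27 and 2.66 ± 2.55 TPM, Cd79b at 73.4 ± 62.1 and 101 ± 71.6 TPM and Ighm at 57.9 ± 40.0 and 109 ± 65.1 TPM. Natural killer cell (0.7995), neutrophil (0.2717) and dendritic cell (0.9171) genes were not called either, nor were those of the interferon gamma response (0.2021), class II antigen presentation (0.731), mitosis (0.8253) and glycolysis (0.3515). In 5 of the uncalled lists, the median, the mean and the test differed in sign. These were the colon epithelium, dendritic cell, inhibitory receptor, early lymphocyte activation and cholesterol synthesis lists. The 6 lists with fewer than 3 tested members included fibroblast and stroma genes, of which Sparc, a matrix protein, passed when adjusted over the list alone. It stood between 2.77 and 25.7 TPM in the non-trogocytic libraries and was listed at 0 in 3 trogocytic ones and at 1.04 TPM in replicate 2.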

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

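The rule for a library that lies far from the other 3 of its group was set in advance, but the genes it was applied to were chosen after the results had been seen. It compares the gap to the nearest library with the range of the group, for 65 named genes, 41 list means and 4 library measures in each group. Of 220 groups tested, 9 passed, against about 11 by chance, so the number of such libraries is no larger than chance gives.

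Among genes, on the log2 scale, Dynap in trogocytic replicate 4 stood at 61.2 TPM, against 76.9 to 80.5 TPM in the other trogocytic libraries, a gap of 0.834 of the range. Oit1 stood at 0.869 TPM in trogocytic replicate 4 and was listed at 0 in the others, and Sparc stood at 1.04 TPM in trogocytic replicate 2 and was listed at 0 in the others, so that the gap was 1 of the range in both. Ighm stood at 3.21 TPM in non-trogocytic replicate 4, against 58.7 to 98.5 TPM (0.839). Tox was listed at 0 in non-trogocytic replicate 4, against 4.49 to 5.21 TPM (0.933). Pvr was lowest in non-trogocytic replicate 1, at 1.01 TPM against 9.73 to 14.0 TPM (0.833), and in trogocytic replicate 2, at 14.0 TPM against 17.0 to 17.6 TPM (0.857). Among list means, DNA replication in trogocytic replicate 1 was 4.21, against 4.87 to 4.97 (0.859), and heat shock in the same library was 6.15, against 6.70 to 6.79 (0.859).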

How the results depend on the processing

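Leaving out the first replicates of both groups, Ptprc as a covariate and the alternatives for list means were chosen after the data had been seen. The count of 6 called genes became 2 with a pseudocount of 0.01, 1 with no filter and 1 without the mean-variance trend, and 0 without the first replicates of both groups (limma, with 594 at an unadjusted p below 0.05). It lay between 0 and 3 with 1 library left out, where fewer samples are fitted. It was 4 to 6 under the other unpaired alternatives. With the replicate block it was 0, and 0 with the block and median-of-ratios scaling (654 and 647 genes at an unadjusted p below 0.05). The labels give both groups the same replicate numbers. Deviations from the group means of same-numbered libraries correlated at 0.235, 0.005, 0.062 and −0.093. Non-trogocytic replicates 1 and 3 correlated best with their own number, and replicates 2 and 4 with trogocytic replicates 4 and 3. Such weak correlations neither establish nor exclude a pairing, so the block fits with 0 calls cannot be set aside. Apart from the loss of filtered genes, the 6 genes kept their sign in each setting. With 1 library left out, Ccl6 was still called in 4 of 8 fits, Gm3776 in 3, Gsta1 in 1 and the others in 0. The log2 fold changes in those fits ran from −3.06 to −2.62 for Ccl6 and from 1.65 to 1.80 for Gm3776. For Gsta1 they ran from 1.41 to 1.64 and for Spp1 from −1.68 to −1.38. Oit1 was tested in 4 of the fits, at −3.45 to −3.15. The 11 lists became 0 with an estimated correlation and 0 with fry, each with 4 lists at an unadjusted p below 0.05, and 6 to 14 with 1 library left out. The lists of alternative macrophage activation, macrophages, lysosome and type I interferon were called in each of those 8 fits. The difference in distance between and within groups, −0.148, was 0.856 with a pseudocount of 0.1, 0.034 with median-of-ratios scaling and −0.988 to 0.806 with 1 library left out, with exact permutation p-values of 0.3714 to 0.6. Of the named genes, Vsir turned to −0.0078 with FPKM, −0.011 and −0.023 with pseudocounts of 0.1 and 0.01 and −0.22 with Ptprc as a covariate, Cd8a to −0.10 without the first replicates and Epcam to 0.064 with Ptprc as a covariate. With 1 library left out, the log2 fold changes ran from −0.40 to 0.39 for Vsir, −0.046 to 0.43 for Krt18, −0.23 to 0.10 for Epcam and −0.17 to 0.84 for Havcr2. None of these was called, and the cause was not tested. Ighg3 passed with a pseudocount of 0.1 (adjusted p = 0.0421) and with Ptprc as a covariate (0.0293). The fitted fold changes of Oit1 and Ighg3, listed at 0 in most or all trogocytic libraries, depend on the pseudocount. The cause of these zeros was not tested.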

Other observations

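All tests given from here on were chosen after the results they bear on had been seen. Families of genes with the same symbol stem were tested with camera, 313 in all. With the preset correlation 4 passed, with an estimated correlation 0 did (adjusted p = 0.99 for each, 5 families at an unadjusted p below 0.05). The Zscan family stood higher in trogocytic co-cultures (adjusted p = 0.0134), through Zscan4 genes, which are known from cleavage-stage embryos and stem cells and are near-identical copies. Zscan4d stood at 1.77 ± 2.23 and 8.28 ± 2.90 TPM (SD, n = 4 each) and Zscan4f at 1.17 ± 1.25 and 5.46 ± 1.64 TPM. Serpinb genes, which encode inhibitors of proteases, stood higher in 10 of 11 cases (0.0134), among them Serpinb2 at 45.4 ± 26.5 and 105 ± 16.5 TPM and Serpinb9b at 95.2 ± 25.1 and 173.5 ± 33.3 TPM. Gstm genes, glutathione transferases of another class than Gsta1, stood lower in 5 of 6 cases (0.00422), among them Gstm5 at 226 ± 30.4 and 130 ± 31.7 TPM and Gstm1 at 207 ± 89.3 and 104 ± 16.3 TPM. Joining segments of the T cell receptor beta chain, Trbj, stood higher in 11 of 12 cases (0.00422). Of these, Trbj2-6 is shorter than 1 read, so its level rests on few reads.

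Values that belong to no comparison include Ifng and Il10, which were listed at 6.17 and 8.19 TPM in trogocytic replicate 1 and at 0 in the other 7 libraries. Gapdh stood at 51.5 to 151.5 TPM and Actb at 11340 to 25620 TPM.

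Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many as 6 genes, and the highest of the others called 5, a margin of 1 gene in a count that fell to 0 to 3 with 1 library left out. Taken alone this count passes, with a share of 0.0286, the smallest possible, but it would not pass when adjusted over the 4 counts taken from these splits, so chance is not firmly excluded. As many as 525 genes at an unadjusted p below 0.05 came from 18 of the 35 splits (highest other 1366), and as many as 306 genes without overlap from 15, so for these counts chance cannot be excluded. For the 11 lists called with the preset correlation, 13 of the 35 splits called as many, with a highest other count of 29, so chance cannot be excluded. A split with 29 lists points to a structure of the libraries other than the groups.

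With the preset correlation, macrophage lists were called lower in trogocytic co-cultures and T cell lists were not. Fewer leukocytes of every kind would lower both alike. The macrophage list mean minus the pan T cell list mean differed by −1.305 ± 0.282 (SE) on the log2 scale. It was lower in 4 of 4 trogocytic libraries than in any other (exact permutation p = 0.0286, the smallest possible, 0.0429 adjusted over 3 such tests). The 2 lists were picked after one had been seen to fall and the other to rise, and the adjustment leaves that choice out. Alone, their means differed by −0.63 ± 0.49 and 0.68 ± 0.61 (exact permutation p = 0.2857 and 0.3429). The difference thus restates what was seen and does not decide the question. The activation list, without the 2 members that both lists hold, dropped by more than the macrophage list (−0.98 ± 0.33), but the exact permutation p of 0.0571 missed the threshold, so fewer macrophages as the whole cause stays open. No biological explanation was tested.

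Gsta1 and Gm3776 rose and Gsta2 stood higher in trogocytic co-cultures. Reads moved only among Gsta1, Gsta2, Gm3776, Gm10639 and Gsta4 would leave their summed TPM as it was. That sum was 479 ± 27.0 and 947.5 ± 89.6 (SD, n = 4 each, exact permutation p = 0.0286, 0.0429 adjusted). Since 3 of the 5 genes were chosen for their rise, this p adds no support of its own. Reads moved from genes outside these 5 were not tested. A larger share of epithelial RNA would raise the epithelial list as much, apart from its low genes, whose change the log2(TPM + 1) scale understates. The upper 95% bound of that list's difference was 0.915, below the smallest of the 3 fold changes, 1.47, that of Gsta2. The 3 genes were chosen for their rise, and the lower 95% limit of Gsta2 was 0.948. This comparison thus does not firmly exclude that cause. The oxidative stress response list was not called (camera adjusted p = 0.3274) and Gstm genes stood lower in 5 of 6 cases. No biological explanation was tested. A difference between batches of sorted cancer cells was not tested.

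Trbc1 was little related to the other T cell genes. It spanned 1.93-fold over the 8 libraries, against 8.58-fold for Trbc2, 17.9-fold for Trac and 35.4-fold for Cd3e. Tigit spanned 2.49-fold. Of 4 relations with the mean of 16 other T cell markers, Trbc1 gave Pearson's r = 0.15 (exact permutation p = 0.7188, adjusted 0.7188; Spearman's rho = 0.286, p = 0.5008), Trbc2 r = 0.886 (p = 0.00315, adjusted 0.0108; rho = 0.81, p = 0.0218) and Tigit r = 0.354 (p = 0.3938, adjusted 0.5251; rho = 0.071, p = 0.882). The log2 ratio of Trbc2 to Trbc1 followed the other markers as well (r = 0.881, exact permutation p = 0.00538, adjusted 0.0108; rho = 0.738, p = 0.0458, adjusted 0.0917). The ratio was chosen once both genes had been seen, so it restates their relations and decides nothing. The 2 libraries farthest from the median were non-trogocytic replicate 4 and trogocytic replicate 1. Without them, r was 0.686 for the ratio (exact permutation p = 0.1444), 0.669 for Trbc2, −0.006 for Trbc1 and −0.369 for Tigit. A test on fewer libraries is weaker, so how far the relations rest on those 2 cannot be judged. In non-trogocytic replicate 4, Trbc1 stood at 208.6 TPM beside Trbc2 at 26.3, Trac at 18.0 and Cd3e at 1.47 TPM. In non-trogocytic replicate 1, Trbc1 stood at 161.3 TPM beside 176.1, 120.6 and 51.9 TPM. With the narrow span of Trbc1 over the 8 libraries, these values argue against T cell number alone setting Trbc1. Whether it sets Trbc2 stays open.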
